A study of Arabidopsis thaliana with 4 samples.

How the data were processed

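Small RNA from Arabidopsis thaliana pollen (ecotype Col-0) was sequenced in 4 libraries, 2 labelled mir845 1n and 2 labelled mir845 2n. Per the labels' protocols, pollen was shaken out of flowers in sucrose solution and filtered, total RNA was run on a gel, and RNA of 17 to 25 nt was taken for a TruSeq small RNA library. The labels do not say what mir845 stands for (a mutant, a transgene or the focus of the study), how the 2n pollen was obtained, or whether the 2 replicates of a group came from separate plants. No library without the mir845 label is part of the series. The p-values therefore measure the difference between the groups against the spread of these 4 samples only.

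Each library has 2 files. The first, as deposited, holds a read count per distinct read sequence; its adapters were already removed, no header or label describes the trimming, and its reads are 18 to 30 nt long. The second, per the file headers, holds a value called RPM per locus and read length (20 to 24 nt). It was treated as a normalised signal, because the deposited values sum to between 1762946 and 2087223 per library, more than RPM over all reads adds up to when each read is counted 1 time. The submitters' processing notes name Bowtie without a version and the TAIR10 genome. How the authors divided reads with several positions, and what their RPM denominator was, is not stated in the labels.

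All comparisons were computed from the read counts. Reads of 18 to 25 nt were placed on the nuclear and organellar chromosomes of the RefSeq assembly TAIR10.1 at every exact match (numba 0.67.0, numpy 2.4.6, pandas 2.3.3, Python 3.11.15), and a read with several positions was divided equally over them and assigned by its middle base. Each sequence got the first class that any of its positions fell in, in the order rRNA, tRNA, snRNA or snoRNA, miRNA hairpin, TAS locus, mitochondrion or chloroplast (genomes that share no position). For class shares and levels, the remaining reads were divided over protein-coding genes, transposon genes, other genes and unannotated sequence, genes before transposons. For rRNA, 6300 nt from the start of each annotated 18S gene were taken as a 45S unit, and 106 copies of the 5S gene were found by a core sequence. Locus types come from the deposited tables: of their 32239 loci, 31903 were found in the annotation, including all 3881 transposon genes. The reference annotation names no transposon families or superfamilies, so the 9 lists of families that had been fixed could not be tested, and transposons were tested per transposon gene.

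The 5 count tables were mature miRNAs (reads identical to 1 of 350 annotated mature sequences), 21-22 nt reads per transposon gene, 24 nt reads per transposon gene, 21-22 nt reads per nuclear gene including TAS loci, and distinct sequences with at least 10 reads in total. Reads of rRNA, tRNA, snRNA, snoRNA and miRNA hairpins were left out of the transposon and gene tables, and divided counts were rounded. Each table was tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, TMM scaling within the table, the filterByExpr filter and no covariate, and features with a Benjamini-Hochberg adjusted p below 0.05 are called higher or lower. Fold changes are log2 of 2n over 1n with the standard error (SE) that the quasi-likelihood F gives. CPM values are counts over the total of the tested table after TMM scaling, and rpm values are reads over all mapped 18-25 nt reads, both in their usual units. Because TMM centres each table on its own bulk, a change shared by nearly all features of a table is removed by it, and is given as rpm and with scaling to all mapped reads. Shares and levels of classes are values with no test: with 2 libraries against 2 there are 3 splits of the libraries, and the smallest two-sided exact permutation p is 0.333.

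Fixed lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. There were 9 tests, adjusted together: 6 lists of miRNA families, the TAS loci, and transposon genes whose sense strand holds a site complementary to miR845a or miR845b with at most 4 mismatches (11 transposon genes), for 21-22 nt and for 24 nt reads. In the text, features are named by a fixed rule: in each table the 10 largest fold changes per direction among features past the threshold whose groups do not overlap, or, where fewer than 5 pass, those of lowest p up to 5, said not to pass; miR845a and miR845b, the 5 most abundant miRNAs and the TAS loci; and 2 members of each list by abundance. An exception was made for distinct sequences: those that were higher in 2n pollen are not printed, because many have no match in the Arabidopsis genome or lie in conserved rRNA and tRNA. The samples, tests, lists, naming rule and other settings were fixed before the data were examined.

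The other settings were DESeq2 1.42.0 with its size factors, edgeR scaled to all mapped reads without TMM, no low-count filter, the replicate number as a block, leaving out each library, counting miRNA variants of up to 2 nt at the 3′ end, reads with 1 position only, other denominators for shares, and transposons before genes. Added after the data were examined were limma on log2 of the deposited RPM plus 0.5 over loci with a mean RPM of at least 1, the distinct sequences with an exact genomic match only, a crossed pairing of the replicate numbers, and leaving out libraries for the miR845 levels. The division of reads with several positions was compared with the deposited table: over 22636 to 28762 loci per library, the Spearman correlation of own counts with deposited RPM was 0.935 to 0.948 (across loci, which are not independent replicates). Reads without an exact match were searched again with bwa 0.7.19 allowing 1 mismatch, with their reversed sequences as a control. Structures were folded with RNAfold 2.7.2. Intervals of single counts are exact 95% Poisson intervals, and they cover counting error only, since PCR copies of a read are not independent molecules.

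The edgeR step was tested on simulated counts drawn from the means, library sizes and dispersions of the real tables. A simulated log2 change of 1 was recovered for 88.9% of 9 changed miRNAs, 56.8% of 95 transposon genes at 21-22 nt, 47.4% of 97 transposon genes at 24 nt, and 51.6% of 95 genes. A change of 2 was recovered for 100% of 10 miRNAs, 98.0% of 99 and 94.9% of 99 transposon genes, and 94.9% of 98 genes. For distinct sequences, a change of 2 was recovered for 7.14% of 98 and a change of 6 for 97.0% of 100. There 200 of 81090 sequences were changed, far fewer than the 16038 called in the real table, so this recovery does not carry over to it. False calls made up 0% to 5.96% of the calls. The counts followed edgeR's own model and dispersions, so this rate does not show whether those dispersions are right with 2 libraries per group.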

Results

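Small RNA of pollen was read in 2 libraries labelled mir845 1n and 2 labelled mir845 2n. The 1n libraries held 29933458 and 40362396 reads, and the 2n libraries 23999663 and 47154652. Of the 18-25 nt reads, 88.9% and 88.2% matched the Arabidopsis genome exactly in 1n pollen, against 85.8% and 71.5% in 2n pollen, which left 20006163, 26424381, 16607583 and 28010664 mapped reads. At these depths a sequence seen 0 times is below 0.107 to 0.181 rpm. The series title ties microRNA-triggered small RNAs of transposons to genome dosage, so the comparison asks how small RNAs differ between pollen of the 2 ploidies.

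miR845a and miR845b, the annotated mature miRNAs of that name, were read in every library, and neither passed a test between the groups when set against other miRNAs; scaled to all mapped reads, miR845a passed as lower in 2n (log2 -1.06) and miR845b (-0.77) did not pass. They lie on chromosome 4 of TAIR10.1, miR845a (AT4G23387, 21 nt) at 12217457 to 12217477 and miR845b (AT4G23375, 22 nt) at 12214086 to 12214107, both on the minus strand. miR845a stood at 138 rpm (95% interval 133 to 144) and 167 rpm (162 to 172) in the 1n replicates, and at 55.9 rpm (52.4 to 59.7) and 90.8 rpm (87.3 to 94.3) in the 2n replicates. miR845b stood at 65.6 rpm (62.1 to 69.3) and 78.0 rpm (74.6 to 81.4) in 1n, and at 32.6 rpm (29.9 to 35.5) and 51.6 rpm (49.0 to 54.4) in 2n. Within the miRNA table, miR845a went from 9562 ± 512 to 8379 ± 201 CPM (SD, n = 2; log2 -0.19 ± 0.11 SE) and miR845b from 4499 ± 189 to 4826 ± 29.4 CPM (log2 0.10 ± 0.12). Neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.316 and 0.639). The lower rpm values in 2n are shared by miRNAs as a class: all reads of miRNA hairpins stood at 19420 ± 2211 rpm in 1n and 11939 ± 3797 rpm in 2n.

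Small RNAs of transposon genes, TAS loci and miRNA hairpins made up less of the mapped reads in 2n than in 1n pollen, and tRNA fragments made up more. Transposon genes held 3029 ± 378 rpm of 24 nt reads in 1n and 1443 ± 239 rpm in 2n (SD, n = 2), a ratio of 0.476. Their 21-22 nt reads stood at 1659 ± 225 and 1179 ± 181 rpm, a ratio of 0.711. TAS loci, which give trans-acting siRNAs, held 1384 ± 197 and 726 ± 233 rpm of 21-22 nt reads, and tRNA fragments 24817 ± 1950 and 32589 ± 5348 rpm. Set against miRNA hairpin reads in place of all mapped reads, the ratios were 0.795 for 24 nt and 1.19 for 21-22 nt reads of transposon genes and 0.854 for TAS loci, so the direction of the 21-22 nt reads turns with the denominator, and all transposon reads (0.995) overlapped. Per mapped read, in these 4 classes and in miRNA hairpins both 2n libraries lay on the same side of both 1n libraries. The exact permutation test of 2 against 2 cannot give a two-sided p below 0.333. Protein-coding genes held 19642 ± 1055 and 17453 ± 2222 rpm of 21-22 nt reads, and rRNA fragments 82.0 ± 1.54% and 83.0 ± 2.57% of mapped reads; for both the groups overlapped. The fall was not limited to siRNA and miRNA classes. Mitochondrial reads went from 2.14 ± 0.209% to 1.42 ± 0.290% of mapped reads, a ratio of 0.664. Reads of snRNA and snoRNA rose, with a ratio of 1.65. In neither of these did the groups overlap.

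**Figure D1:**
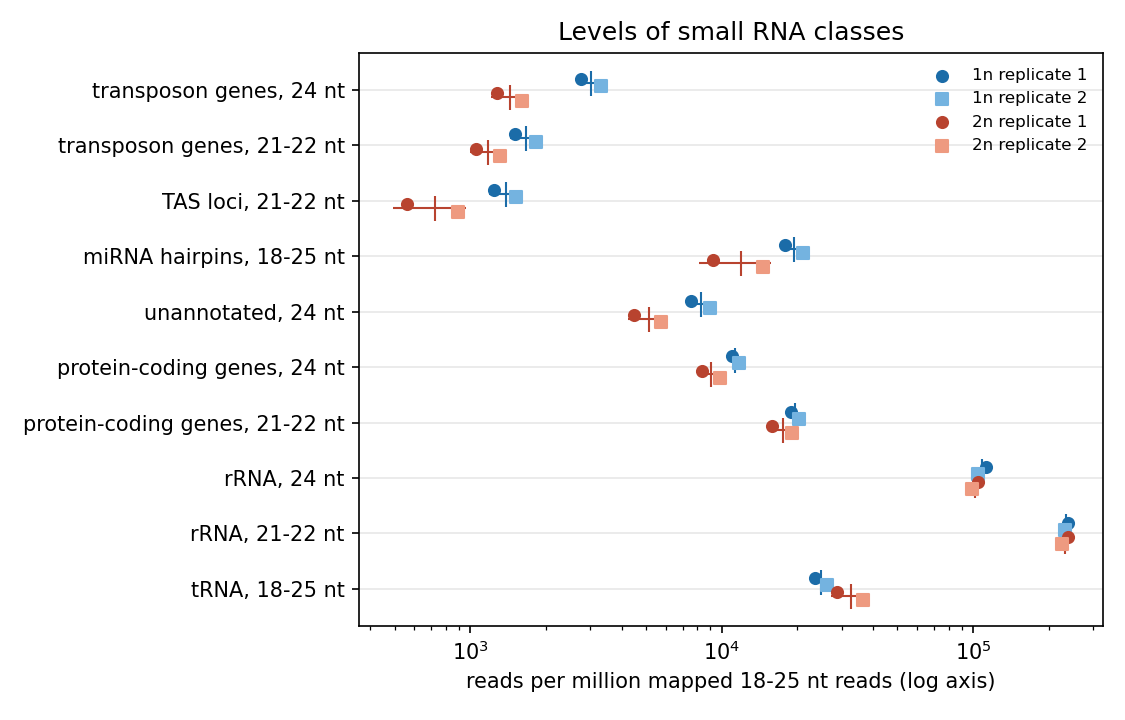
Reads in rpm (horizontal log axis) of small RNA classes in each of the 4 libraries, with a tick and bar for the mean and SD of each group (n = 2). The 24 nt reads of transposon genes stand at 2762 and 3296 rpm in 1n and at 1274 and 1611 rpm in 2n pollen.

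The share of 24 nt reads at transposon genes was lower in 2n pollen, and that of every length from 18 to 23 nt was higher. Of reads at transposon genes, 24 nt reads made up 45.6 ± 0.134% in 1n and 36.5 ± 0.252% in 2n (SD, n = 2), 22 nt reads 13.9 ± 0.00229% and 17.3 ± 0.126%, and 21 nt reads 11.1 ± 0.204% and 12.5 ± 0.0363%. The ratio of 2n over 1n was 1.41 at 18 nt, 1.26 at 19 nt, 1.27 at 20 nt, 1.13 at 21 nt, 1.25 at 22 nt and 1.06 at 23 nt. A lower share at 24 nt raises the shares of the other lengths. Per mapped read, reads at transposon genes were fewer in 2n at every length. At 18 nt they stood at 167 and 208 rpm in 1n and 152 and 159 rpm in 2n. There were 1.83 ± 0.0205 reads of 24 nt per 21-22 nt read in 1n and 1.22 ± 0.0151 in 2n. The deposited RPM, which divides reads by a method of the authors, gave a 24 nt share of 43.9 ± 0.925% in 1n and 34.6 ± 0.445% in 2n over lengths of 20 to 24 nt. Over all mapped reads, rRNA included, the 24 nt share went from 13.7 ± 0.368% to 12.3 ± 0.00895%, and the 18 nt share from 4.71 ± 0.382% to 8.97 ± 0.116%. Each of these differences except that at 23 nt exceeded the gap between replicates. The 23 nt share at transposon genes was 17.6% and 17.2% in 1n and 17.8% and 18.9% in 2n.

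**Figure D2:**
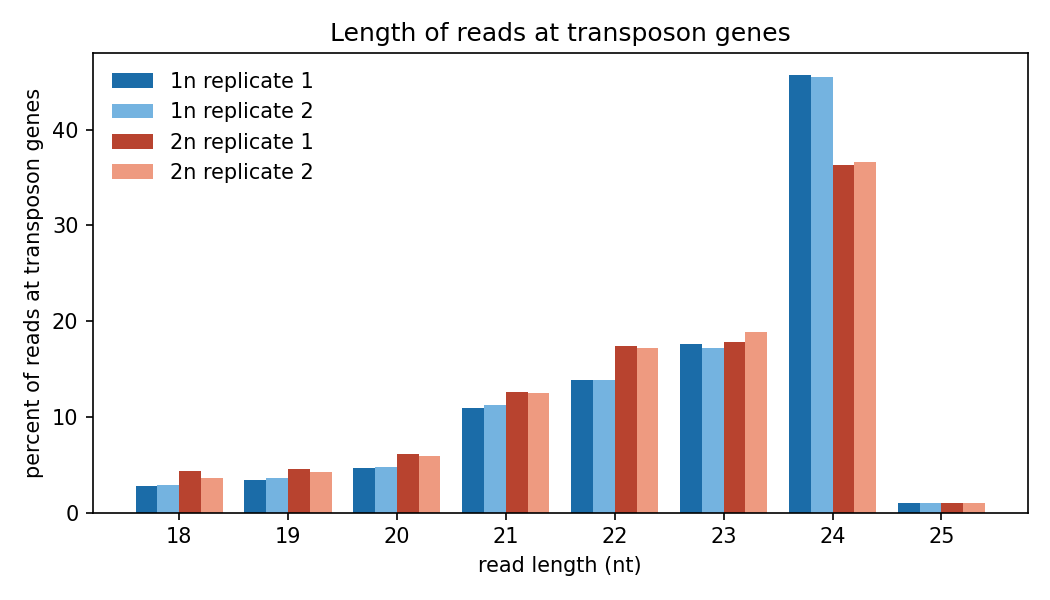
Percent of the reads at transposon genes (vertical axis) that have each length from 18 to 25 nt (horizontal axis), with 1 bar per library. The 24 nt share is 45.7% and 45.5% in the 1n libraries and 36.3% and 36.6% in the 2n libraries.

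Among miRNAs, 8 were higher in 2n pollen and 0 were lower, of 85 tested. miR159a rose from 508 ± 131 to 2100 ± 187 CPM (SD, n = 2; log2 2.04 ± 0.21 SE) and miR319a/miR319b from 587 ± 12.3 to 1794 ± 179 CPM (log2 1.62 ± 0.16). miR780.1 (log2 3.56 ± 0.56), miR771 (2.74 ± 0.53), miR163 (1.80 ± 0.40), miR396a-5p (1.45 ± 0.26), miR159b-3p (1.41 ± 0.32) and miR398b-3p/miR398c-3p (0.99 ± 0.16) also rose. The folds of miR780.1, miR771 and miR163 rest on few reads. In the 1n and then the 2n libraries, miR780.1 stood at 3.32, 2.25, 35.5 and 36.9 CPM. miR771 stood at 13.3, 11.2, 44.3 and 104 CPM, and miR163 at 19.9, 29.2, 79.8 and 93.9 CPM. All 8 were higher in both 2n libraries than in both 1n libraries, with adjusted p from 6.45e-04 to 0.0281 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Before adjustment 26 miRNAs had a p under 0.05, and DESeq2 called 6 higher and 5 lower. The lower miRNAs of lowest p, miR156a to f-5p (log2 -0.51 ± 0.14), miR156b-3p (-0.77 ± 0.21), miR156f-3p (-0.68 ± 0.20), miR5029 (-0.53 ± 0.15) and miR840-5p (-0.82 ± 0.24), did not pass (adjusted p = 0.0534 for each, same test). Of the 5 most abundant, miR165a-3p/miR165b stood at 321144 ± 7169 and 400961 ± 8211 CPM (log2 0.32 ± 0.10), and miR166, miR158a-3p, miR158b and miR156 had log2 folds of 0.52, -0.19, -0.34 and -0.51; none passed.

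With scaling to all mapped reads in place of the miRNA table, the median log2 fold of the miRNAs moved from 0.06 to -0.83, and the calls became 1 higher and 22 lower. miR159a was the 1 that stayed higher (log2 1.18), while miR163 (log2 0.97), miR319a/miR319b (0.77), miR159b-3p (0.59), miR396a-5p (0.51) and miR398b-3p/miR398c-3p (0.09) had smaller folds and did not pass; miR780.1 and miR771 were not among those tested in that setting. Changes of single miRNAs are therefore relative to the other miRNAs. Without 2n replicate 1 the calls were 13 higher and 9 lower, and without 2n replicate 2 they were 14 higher and 6 lower, so the count depends on each 2n library. The higher calls were 5, with 1 lower, without 1n replicate 1, and 6, with 2 lower, without 1n replicate 2. Of the 8 miRNAs, 7 and 4 stayed past the threshold in these settings, and 4 and 5 without 1n replicate 1 and 1n replicate 2; miR159a, miR319a/miR319b and miR396a-5p did so in all 4. The log2 fold of miR159b-3p was 0.87 without 2n replicate 2. miR156a to f-5p passed as lower without 1n replicate 2 (log2 -0.64), 2n replicate 1 (-0.66) or 2n replicate 2 (-0.33), and miR165a-3p/miR165b and miR166 passed as higher without either 2n library.

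**Figure D3:**
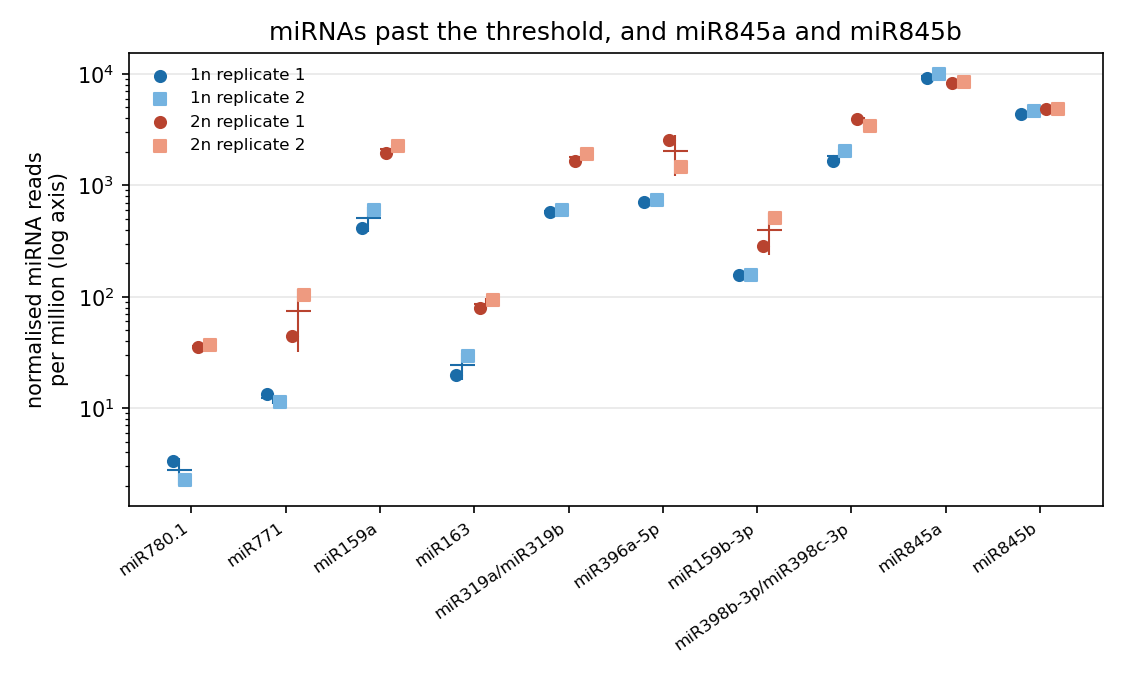
Normalised miRNA CPM (vertical log axis) in each library for the 8 miRNAs that were higher in 2n pollen, and for miR845a and miR845b, with the mean and SD of each group (n = 2). miR159a stands at 416 and 600 CPM in 1n and 1968 and 2232 CPM in 2n; scaled to all mapped reads, only miR159a passed of the 6 that were tested.

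None of the 6 lists of miRNA families passed as a group. Of 32 conserved miRNAs, 5 rose (miR159a, miR159b-3p, miR319a/miR319b, miR396a-5p and miR398b-3p/miR398c-3p) and 27 did not pass; adjusted over the list alone, 7 were higher and 5 lower. Of 39 miRNAs of Brassicaceae-restricted families, miR158a-3p and miR158b the most abundant, 3 rose (miR780.1, miR771 and miR163, all with few reads) and 36 did not pass, with 3 higher and 0 lower adjusted over the list alone. Of 11 miRNAs abundant in floral somatic tissue, miR165 and miR166 the most abundant, 3 rose (miR319a/miR319b, miR396a-5p and miR163) and 8 did not pass, with 5 higher and 0 lower adjusted over the list alone. None of the 3 22-nt triggers of secondary siRNA (miR845b; miR472-3p, log2 -0.75; miR173-5p) passed, in the whole table or adjusted over the list alone. Likewise none of the 5 miRNAs acting on small RNA pathway genes (miR403-3p, log2 0.03; miR162a-3p/miR162b-3p, log2 0.05; miR168) passed by either adjustment. Of 7 nutrient-responsive miRNAs, 1 rose (miR398b-3p/miR398c-3p) and miR399a (log2 -0.18) did not pass, with 1 higher and 1 lower adjusted over the list alone. Camera in limma gave adjusted p of 0.0958 for the floral somatic list, with a median log2 fold of 0.42, and 0.776 to 0.984 for the other 5. With an estimated correlation the values were 0.796 for the floral somatic list and 0.985 for the others. The floral somatic list passed without 2n replicate 1 (0.0178 in camera).

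For Brassicaceae-restricted miRNAs the median log2 fold was -0.01, the mean 0.21, and camera pointed lower; for miRNAs acting on small RNA pathway genes the median was 0.05, the mean -0.01, and camera again pointed lower. The other medians were 0.21 (conserved), -0.29 (22-nt triggers) and 0.35 (nutrient-responsive). With scaling to all mapped reads every miRNA list had a negative median: -0.78 for conserved (1 higher, 10 lower), -0.88 for Brassicaceae-restricted (0 higher, 11 lower), -0.42 for floral somatic (0 higher, 2 lower), -1.13 for 22-nt triggers (0 higher, 1 lower), -0.83 for small RNA pathway (0 higher, 1 lower) and -0.52 for nutrient-responsive miRNAs (0 higher, 3 lower).

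At transposon genes, 21-22 nt reads differed at 5 of 1007 loci. 2 were higher in 2n pollen, AT2G04460 (chromosome 2, 1547538 to 1548999; log2 2.13 ± 0.43 SE) and AT2G05025 (log2 1.94 ± 0.36). 3 were lower, AT2G13200 (log2 -1.14 ± 0.13), its neighbour AT2G13190 (log2 -1.03 ± 0.13) and AT2G07590 (log2 -0.98 ± 0.13), each with both 2n libraries below both 1n libraries. AT2G13200 (chromosome 2, 5471589 to 5473914) fell from 9976 ± 618 to 4603 ± 263 CPM (SD, n = 2; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.76e-04). The antisense share of the reads was 10.7% at AT2G13200, 97.4% at AT2G13190, 3.63% at AT2G07590, 9.4% at AT2G05025 and 49.8% at AT2G04460. Except at AT2G04460 the reads lay mostly on a single strand, the plus strand for both neighbours. There siRNA is not told apart from fragments of a transcript. Both higher loci depend on 2n replicate 2: AT2G04460 stood at 949, 1131, 1390 and 6473 CPM over the 4 libraries, and without that library its log2 fold was 0.32 and that of AT2G05025 was 0.72, neither past the threshold.

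Before adjustment 77 of the 1007 loci had a p under 0.05, and DESeq2 called 0 (7 before adjustment). Leaving out 1 library gave 0 calls without 1n replicate 1, 3 without 1n replicate 2, 14 without 2n replicate 1 and 9 without 2n replicate 2, of which 0, 2, 5 and 3 were among the 5 loci. With the replicate number as a block 0 passed (61 at an unadjusted p under 0.05 in edgeR). The next loci by p did not pass: AT3G31540 (log2 1.36), AT1G34240 (0.97) and AT2G11240 (0.81) on the higher side, AT2G07580 (-0.79) and AT4G03816 (-1.20) on the lower. When all mapped reads set the scale, the median log2 fold moved from 0.00 to -0.43 and the calls became 0 higher and 4 lower; with the deposited RPM in limma they were 0 higher and 3 lower. Transposon genes with a site for miR845a or miR845b did not pass as a group: of 8 tested, AT4G05585 (log2 -0.02) and AT3G31630 (log2 0.08) among them, 0 passed over the table or adjusted over the list alone, and their median log2 fold was -0.05 (camera in limma, adjusted p = 0.952; 0.985 with an estimated correlation). That median was -0.48 with scaling to all mapped reads. Sites outside the annotated transposon genes, or with gaps or more mismatches, were not searched. Other targets of miR845 may therefore stand among the genes the list was compared with, and the result covers the listed genes only.

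Counted per mapped read, 24 nt siRNAs fell at most of the transposon genes kept by the low-count filter. Few loci moved away from that shared fall. Scaled to all mapped reads, 1380 of 1813 loci were lower in 2n pollen and 0 were higher, with a median log2 fold of -1.04. The deposited RPM in limma gave 1290 lower and 1 higher of 2844 loci, with a median of -0.77. Both counts repeat the same shared shift between the same libraries, so the loci are not independent evidence of it. Set against miRNA hairpin reads, the 2n over 1n ratio of all 24 nt transposon reads was 0.795. Relative to the other transposon genes (TMM, median 0.02), 2 of 1646 loci were higher, AT3G43730 (log2 1.19 ± 0.24 SE) and AT1G54905 (0.73 ± 0.15). Another 4 were lower, AT3G42115 (log2 -4.04 ± 0.80), AT3G29615 (-0.45 ± 0.06), AT2G01037 (-0.41 ± 0.08) and AT5G29075 (-0.41 ± 0.06), with adjusted p from 8.44e-04 to 0.0285 over the 6 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

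AT3G42115 (chromosome 3, 14290248 to 14294330) stood at 349 and 334 CPM in 1n and at 57.0 and 0 CPM in 2n, and its log2 fold was -2.55 without 2n replicate 2, no longer past the threshold; without 2n replicate 1 the 2n library left holds 0 reads, and no fold is given. The log2 fold of AT3G43730 was 0.17 with all mapped reads and 0.32 with the deposited RPM, and that of AT2G01037 was -0.17 with reads of 1 position only, none past the threshold. With reads of 1 position only, or with the replicate number as a block, 0 of the 6 loci passed (68 and 96 loci at an unadjusted p under 0.05 in edgeR). AT1G54905 changed sign with the scaling, to a log2 fold of -0.31 with all mapped reads and -0.14 with the deposited RPM. DESeq2 called 0 loci (16 before adjustment), and in edgeR 110 had an unadjusted p under 0.05. Without 1n replicate 1, 1n replicate 2, 2n replicate 1 and 2n replicate 2 the calls were 4, 0, 12 and 2, of which 2, 0, 5 and 1 were among the 6 loci. The loci next in p did not pass: AT3G29525 (log2 0.55), AT3G29540 (0.52) and AT3G30716 (1.11) on the higher side and AT4G06550 (-0.60) on the lower; scaled to all mapped reads or with the deposited RPM, AT3G29525 and AT3G29540 turned negative, and AT3G30716 did so with the deposited RPM (-0.28) and without 2n replicate 2 (-0.17). Of 9 transposon genes with a miR845 site, AT4G05585 (log2 0.10) and AT3G31630 (log2 0.06) among them, 0 passed over the table or adjusted over the list alone, with a median log2 fold of 0.00 (camera in limma, adjusted p = 0.984; 0.985 with an estimated correlation). With scaling to all mapped reads 8 of the 10 such genes tested in that setting were lower, beside 1380 of all 1813 loci. Sites outside the annotated genes were not searched, so this result too covers the listed genes only.

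At genes and TAS loci, 186 of 3743 loci differed in 21-22 nt reads: 73 were higher in 2n pollen and 113 lower. The TAS loci that miR173 targets fell together: TAS1A (log2 -0.78 ± 0.12 SE), TAS1B (-0.89 ± 0.11), TAS1C (-0.78 ± 0.11) and TAS2 (-0.85 ± 0.10). TAS1C, the most abundant (AT2G39675, chromosome 2, 16537288 to 16538277), fell from 40172 ± 2867 to 23345 ± 5058 CPM and TAS2 from 15187 ± 1494 to 8441 ± 1060 (SD, n = 2). The 4 had adjusted p from 2.64e-05 to 4.10e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and they were lower in both 2n libraries than in both 1n libraries. TAS3 (log2 0.72 ± 0.22) and TAS3b (0.72 ± 0.39) did not pass (adjusted p = 0.0636 and 0.385, same test), and TAS4 is not in the table; without 2n replicate 1 TAS3 passed (log2 0.98).

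Of the 6 TAS loci tested, 4 fell and 2 did not pass; adjusted over the list alone, 4 were lower and 1 higher, with a median log2 fold of -0.78. Camera in limma gave an adjusted p of 1.56e-06 at the preset correlation, which did not hold with the estimated correlation of 0.73 (0.796). Tested against no change in place of the other genes, fry in limma gave an adjusted p of 0.222. Scaled to all mapped reads, the same split of 4 lower and 0 higher had a median of -0.91.

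NRPD1A (AT1G63020, chromosome 1, 23354685 to 23362589), which codes for the largest subunit of RNA polymerase IV, had the largest rise of the tested genes past the threshold, from 5.80 ± 1.33 to 157 ± 139 CPM of 21-22 nt reads (SD, n = 2; log2 4.84 ± 0.61 SE, and 3.22 without 2n replicate 2). LCR11 (log2 2.66 ± 0.35), AT3G02480 (2.61 ± 0.36) and the myosin gene XIE (2.36 ± 0.50) also rose, as did AT2G04115, AT1G52680, AT1G57710, AT1G09075, AT5G53820 and AT2G16750. All these rising genes had few reads in 1n, with means from 3.74 CPM (AT1G09075) to 16.1 CPM (LCR11). Falls came at AT3G10510 (log2 -2.10 ± 0.35), NF-YC5 (-2.06 ± 0.51), AT3G04715 (-1.84 ± 0.29), AT1G15800 (-1.82 ± 0.34), AT2G36180 (-1.63 ± 0.29) and WAVH2 (-1.62 ± 0.36), with AT5G11430, AT5G17730, AT3G07350 and AT3G49601 falling from lower counts. Of these 20 genes, LCR11, AT3G02480, AT3G10510, AT3G04715, AT1G15800, AT2G36180, WAVH2 and NRPD1A passed whichever library was left out. Without 2n replicate 2 the log2 fold was 1.62 for AT1G57710 and -1.06 for AT3G07350, neither past the threshold, and AT5G11430, with 0 reads left in 2n, did not pass either; without 1n replicate 2 it was 3.30 for AT2G16750. When all mapped reads set the scale, the median log2 fold moved from -0.01 to -0.14 and the calls became 25 higher and 103 lower. With the deposited RPM in limma they were 105 higher and 90 lower, and without 1n replicate 2 they were 39 higher and 65 lower. The higher side also depends on 1n replicate 1 (42 higher and 96 lower without it) and 2n replicate 2 (38 and 112). DESeq2 called 21 higher and 43 lower, all of them among the 186.

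Direction went with the strand of the reads, a comparison chosen after the values were seen. Loci with at least 20% antisense reads were 103 of the 113 lower loci (91.2%), 9 of the 73 higher loci (12.3%) and 1042 of the 3557 loci that did not pass (29.3%). Fisher's exact test of lower against higher loci gave a two-sided p of 5.20e-29, and 2.78e-28 without the TAS loci. Neighbouring loci and loci that share reads are not independent, so the p is too small. All loci also come from the same 4 libraries. The p counts loci and not samples, and does not measure a difference between the ploidies. These shares pool the reads of both groups, so reads added on 1 strand change a locus's share as well as its fold; from the reads of 1n pollen alone, 102 of the 113 lower and 12 of the 73 higher loci reached 20% (p 2.22e-25 in the same exact test), and from those of 2n pollen alone 102 and 9. Over all loci tested, the median log2 fold was -0.26 at 1154 loci with reads of both strands and 0.08 at 2589 loci with mostly sense reads. Scaled to all mapped reads, 96 lower and 2 higher loci had reads of both strands, and with DESeq2 40 lower and 1 higher. Values of short fragments moved in the same direction as the mostly sense loci: in 2n over 1n, the 18 nt share of mapped reads had a ratio of 1.90 (2.46 without rRNA and tRNA), tRNA fragments 1.31, and 21-22 nt reads of protein-coding genes per miRNA hairpin read 1.49, though 0.889 per mapped read with overlapping groups. Long reads fell at the same time, at 28 nt from 5.87% and 6.87% of all reads in 1n to 2.53% and 2.76% in 2n. The 18 nt rise is therefore not told apart from a shift of the whole length window.

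**Figure D4:**
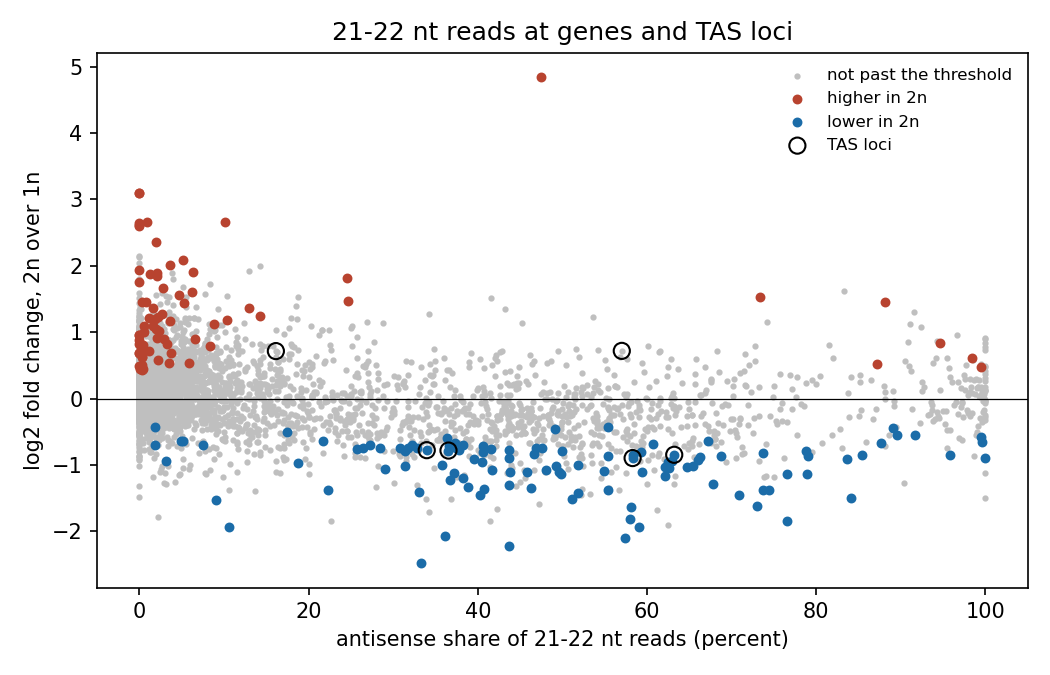
Log2 fold change of 21-22 nt reads, 2n over 1n (vertical axis), against the antisense share of these reads (horizontal axis, percent) for 3743 loci; coloured points passed the threshold, and rings mark the 6 TAS loci. Most of the 113 lower loci lie above 20% antisense reads, and most of the 73 higher loci lie below.

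Distinct sequences, counted without any annotation, gave 14265 that were higher in 2n pollen and 1773 that were lower, of 81090 tested. Most of the higher ones, 10703, have no exact match in the Arabidopsis genome. Of the 56533 sequences with a match, 3562 were higher and 1079 lower, and rRNA (2765 higher, 678 lower) and tRNA (378 higher, 8 lower) gave most of the higher ones. Of 513 sequences of miRNA hairpins 16 were higher and 43 lower, and of 235 of TAS loci 1 was higher and 16 lower; many are overlapping variants of the same loci, and these splits were not tested. The 10 lower sequences with the largest folds had few reads, given here for the 1n and then the 2n libraries. Of 24 nt, ACCCCCTTTCCGACCAACAACTCT (14, 17, 0 and 0), AAGGGAAATCATGCGGGCTAAGCT (10, 13, 0 and 0), ATCCTCTACACTCCATCGAACCGT (21, 34, 0 and 2), AGACACAAAGCCAAAGACTCATAT (9, 18, 1 and 1) and GGCCAGGTTGTTTTAGGAGAAAAC (11, 15, 0 and 2) have from 2 to 100 positions, and GATATTACTAAGTTTGGAGCCGTA (9, 19, 1 and 1) lies at AT1G02790, a pollen polygalacturonase gene. The others are GGGCTTGACCATATGGACA (9, 20, 0 and 1; 7 positions), the rRNA sequence ATCATTGTCGATACCTGTCCAA (16, 22, 0 and 2), and AAACTCGGTGTACATAGACCA and ACAAACTCGGTGTACATAGACC (11, 12, 0 and 1 each) of the miRNA hairpin AT2G41616. The counts depend on each of the 4 libraries: without 2n replicate 1, 69408 were higher and 7354 lower of 176712 tested, and without 1n replicate 2 the counts were 7637 and 106 of 149357. They were 13212 and 502 without 1n replicate 1, and 15829 and 6884 without 2n replicate 2. Among sequences with an exact match only, tested alone, 5720 were higher and 1358 lower.

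**Figure D5:**
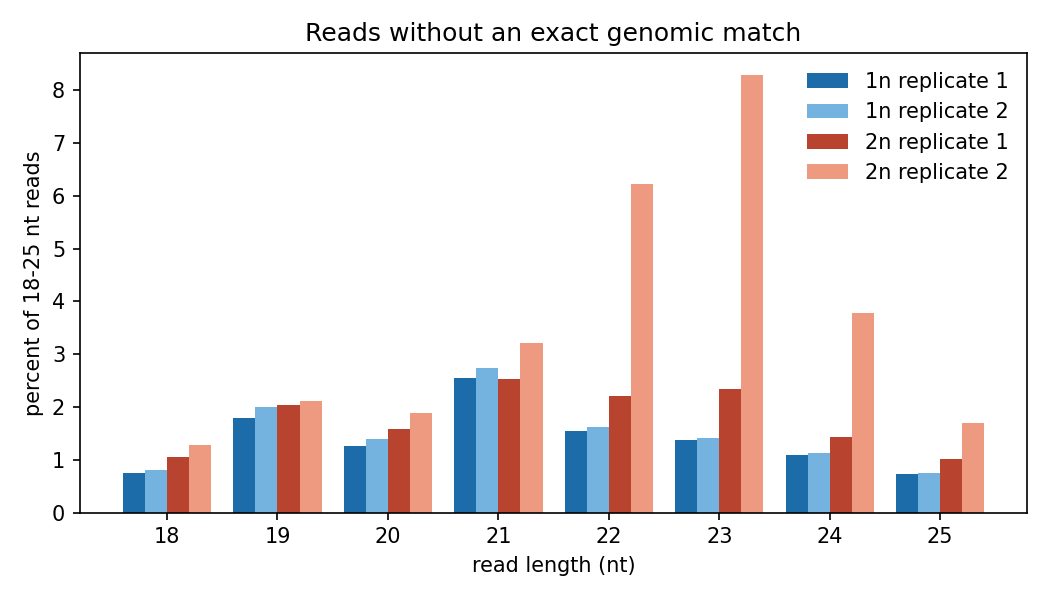
Percent of all 18-25 nt reads (vertical axis) that have no exact match in the Arabidopsis genome, by read length (horizontal axis), with 1 bar per library. At 23 nt the values are 1.38% and 1.42% in the 1n libraries and 2.33% and 8.29% in the 2n libraries.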

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

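The test of the source of the reads without a genomic match was set before its result was seen. The comparisons of the unannotated sequence were chosen after its counts were seen.

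Reads of 22 and 23 nt that match the Arabidopsis genome neither exactly nor with 1 mismatch stood out because no comparison of the genome-based tables uses them. They made up 1.84% and 1.90% of the 18-25 nt reads in the 1n libraries, 3.55% in 2n replicate 1 and 13.6% in 2n replicate 2. Sequence variants or errors of Arabidopsis small RNAs are argued against as the main source in 2n replicate 2. Of all its 22-23 nt reads without an exact match, 6.53% gained a match with 1 mismatch. That share was 21.9% in 2n replicate 1 and 36.9% and 37.4% in 1n. Small RNAs of another organism in the preparation are a candidate source, since 87.6% of the unmatched reads of 2n replicate 2 start with U and they spread over 1381662 distinct sequences. The share starting with U was high in 1n as well (81.6% and 80.5%), and lowest in 2n replicate 1 (75.1%), so by itself it does not set the 2n libraries apart. The pools differ in spread, however. The 100 most abundant sequences held 51.3% and 54.7% of these reads in 1n, 19.5% in 2n replicate 1 and 5.09% in 2n replicate 2. A few sequences thus weigh heavily in the 1n share. The organism was not sought, and a difference between 1n and 2n pollen stays open as untested.

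The most abundant sequence outside every annotated class, TCCGCTGTAGCACACAGGCC (chromosome 5, 4162131 to 4162150, plus strand, and 1 further position), stood out because no count of miRNAs, genes or transposon genes holds it. Among the annotation classes it was counted as unannotated. It was read 41846 and 63683 times in 1n and 87993 and 135900 times in 2n pollen, 2251 ± 225 against 5075 ± 316 rpm (SD, n = 2), a ratio of 2.25. The 74 nt that start with it fold at -21.3 kcal/mol, and 0 of 100 shuffled sequences reached that value. A sequence that starts with the same 13 bases, TCCGCTGTAGCACTTCAGGCT (chromosome 1, 6926868 to 6926888, minus strand), stood at 434 ± 46.1 and 1208 ± 146 rpm, a ratio of 2.78. Forms of other lengths with the same start had other ratios, 7.71 at 18 nt and 1.38 at 19 nt for the chromosome 5 sequence, and 14.8 at 18 nt and 4.03 at 24 nt for that of chromosome 1. No explanation of either was tested.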

How the results depend on the processing

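The deposited RPM in limma, the sequences with an exact match only, the crossed pairing and the miR845 levels without single libraries were chosen after the data were seen. Where 1 library was left out, its group had 1 sample, which was assumed to vary like the other group. Except where said, the cause was not tested.

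Over the 73 named features, values of features past the threshold kept direction and side in 273 cases and fell short in 116, and values of the others stayed short in 188 and passed in 61; 36 values of 13 features reversed. TAS1A, TAS1B, TAS1C and TAS2 stayed lower and past the threshold in each setting run for them.

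The 8 miRNA calls (0 lower) became 23 with scaling to all mapped reads (22 lower), 23 with no low-count filter (11 lower), 18 with the replicate number as a block (5 lower) and 37 with 3′ variants (12 lower), so the absence of lower calls ends in each, and 6 to 22 when 1 library was left out. The 5 calls of 21-22 nt reads at transposon genes became 0 in DESeq2 (7 at an unadjusted p under 0.05), 9 with no filter, 0 with the block (61 unadjusted in edgeR) and 3 with the deposited RPM, and 0 to 14 without 1 library. The 6 calls at 24 nt became 0 in DESeq2 (16 unadjusted), 1380 with scaling to all mapped reads, 0 with the block (96 unadjusted in edgeR), 0 with reads of 1 position (68 unadjusted in edgeR, and fewer loci tested) and 1291 with the deposited RPM, and 0 to 12 without 1 library. The count of 1380 arises because that setting does not remove the shared fall, as TMM does; the deposited RPM differs in read division, tool and filter as well, and the cause of its count was not tested. The 186 calls at genes became 64 in DESeq2 and 104 to 244 without 1 library, with 170 to 195 for reads of 1 position, no filter and the deposited RPM, and 128 and 146 for scaling to all mapped reads and the block. The 16038 distinct sequences became 7078 with an exact match only, where fewer were tested, and 7743 to 76762 without 1 library. Pairing the replicate numbers crosswise gave 22341 calls, against 18514 when paired as numbered. Of the fixed lists, 1 passed, and 0 did with an estimated correlation, 0 in fry, which tests against no change, and 1 to 2 without 1 library.

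The 2n over 1n ratio of the 24 nt share of mapped reads, 0.897, became 0.792 without rRNA and tRNA and 0.775 for distinct sequences. The ratio of miR845a in rpm, 0.480, became 0.802 per miRNA read, and that of miR845b, 0.587, became 0.982, since miRNA reads as a class were fewer in 2n. The transposon share (0.595) was 0.596 with transposons before genes.

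The reversed log2 values follow. With scaling to all mapped reads, which moves a whole table down: AT1G54905 -0.31, AT3G29525 -0.48, AT3G29540 -0.56, AT4G05585 -0.96 and AT3G31630 -0.98 at 24 nt, AT3G31630 -0.35 at 21-22 nt, and miR845b -0.77, miR165 -0.55, miR166 -0.30, miR403-3p -0.83 and miR162 -0.83. With the deposited RPM: AT1G54905 -0.14, AT3G29525 -0.28, AT3G29540 -0.47, AT3G30716 -0.28, AT4G05585 -0.76 and AT3G31630 -0.74 at 24 nt, and AT3G31630 -0.18 at 21-22 nt. With no filter: miR845b -0.046, miR403-3p -0.11 and miR162 -0.10. With 3′ variants: miR845b -0.087, miR403-3p -0.24 and miR162 -0.11. In DESeq2: miR403-3p -0.018 and miR162 -0.0054. With reads of 1 position at 24 nt: AT4G05585 -0.011 and AT3G31630 -0.36. Over the settings without 1 library, the log2 folds ranged from -0.031 to 0.113 for miR403-3p (lowest without 1n replicate 1), -0.024 to 0.115 for miR162 (lowest without 1n replicate 2), -0.30 to 0.074 for AT4G05585 (0.051 without 1n replicate 1, highest without 2n replicate 1) and -0.115 to 0.13 for AT3G31630 at 21-22 nt. At 24 nt they ranged from -0.174 to 1.46 for AT3G30716, -0.143 to 0.188 for AT4G05585 and -0.053 to 0.097 for AT3G31630; these and AT3G31630 at 21-22 nt reversed without 2n replicate 2. Of the 36, those of AT1G54905 belong to a locus past the threshold.

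A test of the distinct sequences with no filter was not run. Depth limits what is seen: a sequence with 0 reads is below 0.107 to 0.181 rpm. Of simulated distinct sequences with a log2 change of 2, 7.14% were recovered, where 200 of 81090 sequences were changed. That is far fewer than the 16038 calls in the real data, so this recovery does not carry over to them.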

Other observations

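The tests of size selection, of dilution and of a shared source with the unmatched reads were chosen after the result was seen, as were the values of NRPD1A and tRNA.

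Reads of 24 nt at transposon genes were fewer per mapped read in 2n pollen, by a ratio of 0.476. Gel size selection is argued against as the whole cause, because the 24 nt over 21 nt ratio at transposon genes, divided by that of rRNA fragments, was 0.757 in 2n relative to 1n. The length window of the libraries did differ. Of all reads, 28 nt reads made up 5.87% and 6.87% in 1n and 2.53% and 2.76% in 2n. For 18 nt reads the values were 3.54% and 3.86% in 1n and 7.12% and 6.35% in 2n. Dilution by more rRNA and other fragments is argued against as the whole cause as well, because 24 nt reads per 21-22 nt read at transposon genes went from 1.83 ± 0.0205 to 1.22 ± 0.0151 (SD, n = 2), a ratio of 0.669. Either may contribute a part. Fragments of rRNA also had fewer 24 nt per 21 nt reads (0.934), though tRNA (1.11) and mitochondrial reads (1.02, groups overlapping) did not. Per mapped read, miRNA hairpins (0.615) and mitochondrial reads (0.664) fell as well. A larger part of degradation fragments among the transposon reads themselves stays open as untested. Their 18 nt share had a ratio of 1.41, but their 18 nt reads per mapped read fell, from 167 and 208 rpm to 152 and 159 rpm. A difference in ploidy or in whatever mir845 denotes in each group stays open as untested too.

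The 8 miRNAs higher in 2n pollen include miR319a/miR319b, miR396a-5p and miR163, which stand on the list of floral somatic tissue. Green floral tissue is not excluded as a source. Reads of 11 leaf mRNAs per read of 8 pollen mRNAs were at most 1.17 times the 1n mean in the 2n libraries. That shows no large rise of such tissue. Scaled to all mapped reads, however, the miRNAs tested also rose less than within the miRNA table. All 11 leaf mRNAs were read in 1n pollen too, so a small input could go unseen. The most abundant, LHCB1.3, stood at 2.84 and 3.69 rpm in 1n and 1.84 and 3.49 rpm in 2n. A shared source with the unmatched 22-23 nt reads, whose excess in 2n replicate 2 was 6.98 times that in 2n replicate 1, cannot be told apart: the median ratio of the excess of the miRNAs was 1.21 among miRNA reads, 1.67 with that excess counted per 18-25 nt read, and 3.18 over the 1n level per 18-25 nt read (0.182 for miR396a-5p to 7.20 for miR771, miR398b-3p/miR398c-3p without an excess in either library, miR159b-3p without one in replicate 1), and which baseline applies is not known. Tissue without green cells, and ploidy, stay open as untested.

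Reads of NRPD1A (18-25 nt) numbered 14 and 10 in 1n and 49 and 392 in 2n pollen, with 7, 7, 19 and 190 of them antisense. In 2n replicate 2 they were 265 distinct sequences, in 16 of the 16 windows of 500 nt along the gene. Fragments of tRNA-Arg stood at 6055 ± 1603 rpm in 1n and 9551 ± 729 in 2n (SD, n = 2), a ratio of 1.58, and those of tRNA-Ala at 5513 ± 246 and 5402 ± 1114 rpm, where the groups overlap.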
